A study of Homo sapiens with 9 samples.

How the data were processed

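RNA was measured by poly-A selected sequencing in 9 libraries of the human melanoma cell line WM3248. Cells received ARN22089 at 0 (vehicle, DMSO), 4 or 6 µM and were harvested 24 h later, with 3 libraries per dose. Groups were taken from the treatment labels and replicate numbers from the submitters' sample names.

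The deposited files are transcript assemblies, 1 per library. Per the submitters' processing notes, the tools were Trimmomatic, TopHat2 2.1, Bowtie2 2.2.7, SAMtools 1.9, Cufflinks 2.2.1 and R 4.0.3, and the lines of the files name Cufflinks as their source. The values in the deposited attribute column are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library), which Cufflinks computed for the authors for each assembled transcript. That column is text that also holds a coverage value and confidence bounds. Each library was assembled separately, with locus numbers of its own and no gene names, and whether an annotation guided the assembly is not given in the sources used here. No scaling between libraries is visible in the files.

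Per the submitters' processing notes the genome build was GRCh37, but the coordinates in the files are those of GRCh38. Over all libraries, 732 transcripts lie on scaffolds whose names exist only in GRCh38, and of 2171 introns on the plus strand of chromosome 20 only 8 (0.37%) have GT and AG ends in the GRCh37 sequence. All coordinates given here are therefore GRCh38.

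Transcripts were given gene names in Python 3.11.15 with pandas 2.3.3. A spliced transcript took the name of the RefSeq gene (GRCh38) that it overlapped on the same strand and with which it shared the most intron lengths, where strands and intron lengths came from the GENCODE annotation and intron lengths do not depend on the build. Of 193769 spliced transcripts over all libraries, 185519 (95.7%) lay in a gene with a matching intron length. A single-exon transcript was used only where at least 50% of it lay in 1 gene that was never assembled with introns. In all, 257156 transcripts were assembled and 15160 genes were named in at least 1 library. The named transcripts held between 89.5% and 95.9% of each library's FPKM times length. Strand came from the splice sites of the assembled transcripts, since the sources used here do not say whether the libraries kept strand, so values of antisense genes and of overlapping genes are uncertain. The same holds for members of near-identical families such as ribosomal protein genes and their pseudogenes.

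A gene's value was the sum of the FPKM of its named transcripts, with 0 where none was assembled. An exact 0 can be a failed assembly. Between 410 and 610 of the tested genes were at 0 in a given library, including between 28 and 53 genes whose median over all libraries was at least 10 FPKM. After the data were seen, a 2nd value was added for this reason, here called the consensus exon value. It is the mean FPKM per base over the exonic bases that a gene's transcripts covered in at least 50% of the libraries that assembled it, summed over all transcripts on those bases whatever their name. Pearson correlations across genes between libraries of 1 dose were between 0.885 and 0.919 with the summed value and between 0.922 and 0.951 with the consensus exon value. Libraries of different doses gave 0.858 to 0.917 and 0.897 to 0.951, so the ranges overlap. Replicate 1 at 0 µM had the lowest values within a dose, 0.885 and 0.892 with the summed value, where all other pairs reached at least 0.905. It also had the most tested genes at 0, 610.

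The files give no read counts, and whole reads cannot be recovered from assembled FPKM, so depth in reads is unknown. The ratio of coverage to FPKM gives the relative depth. Against the median library, it was 0.95, 0.97 and 1.3 in the libraries at 0 µM, 1, 0.98 and 0.8 at 4 µM, and 1.34, 1 and 1.1 at 6 µM. Sums of FPKM lay between 587999 and 689699 in 8 libraries and reached 1061112 in replicate 3 at 0 µM. In that library 2 single-exon transcripts of 100 and 101 bases, on chromosomes 14 and 6, took 21.4% and 17.4% of the sum. Rescaling to a fixed sum (TPM) therefore left the median log2 difference of all genes at 0.32 for 4 µM and 0.24 for 6 µM against 0 µM. As deposited it was 0 and -0.03, and FPKM was kept so.

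Genes with a mean of at least 1 FPKM over the 9 libraries were tested, 12363 in all and 12088 with the consensus exon value. Values were log2(FPKM + 1), so that a fold change understates the change of low genes. All 9 libraries entered 1 limma 3.58.1 fit (R 4.3.3) with a variance prior that follows mean expression, which left 6 residual degrees of freedom. The comparisons were 4 with 0 µM, 6 with 0 µM, and 6 with 4 µM. P-values were adjusted by the Benjamini-Hochberg method at a threshold of 0.05. The design had assumed a table keyed by reference genes, and naming the loci was the added step.

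For 27 gene lists, fixed before the data were examined, limma's camera was run with a preset correlation of 0.01 on the 24 lists with at least 5 measured members. Camera with an estimated correlation and limma's fry were alternatives. P-values of lists were adjusted over the lists of a comparison. For each list the number of members past 0.05 was counted with p-values adjusted over all genes tested and adjusted over the list alone. The lists covered CDC42 family GTPases and effectors, SRF and actin genes, YAP/TAZ-TEAD targets, MAPK output, melanocyte and undifferentiated melanoma genes, replication, mitosis, p53 targets, BCL2 family, ATF4 targets, ER chaperones, heat shock, cholesterol synthesis, lysosome, NF-kB targets, interferon response, extracellular matrix, hypoxia, ribosomal proteins, NRF2 targets, oxidative phosphorylation, markers of 3 other cell types, mitochondrially encoded genes and replication-dependent histones. No mitochondrially encoded gene was named, because the mitochondrial genome was assembled as 1 transcript or not at all.

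Genes named in the text followed a rule fixed before the data were examined, except where the text says that they were chosen after their values were seen. For each dose against 0 µM it takes the 10 largest rises and 10 largest falls among genes past the test whose 3 treated libraries all lay beyond all 3 control libraries and whose mean reached 5 FPKM at 1 of the doses. It leaves out unnamed loci, pseudogenes and genes with only transcripts under 300 bases. It also takes up to 4 passing members of each list, or the 2 members with the smallest p where none passed and the list was called, and always CDC42, RHOJ, RHOQ, PAK1, PAK2, MITF and SOX10. For 6 against 4 µM it takes the 5 largest rises and falls. Means are over libraries, with SD and n = 3.

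The submitters' descriptions give the same date-like tag to libraries of the same replicate number at every dose, which was taken, before the data were examined, to mark a shared day, so that the numbers pair the libraries. Deviations from the dose means, correlated over genes, gave -0.008, 0.017 and 0.033 for the same numbers at 0 and 4 µM, 0.038, 0.042 and 0.032 at 0 and 6 µM, and 0.09, 0.104 and 0.132 at 4 and 6 µM, against -0.091 to 0.018 for different numbers. The fit used for the results had no block, and the fit with the replicate number as a block was an alternative.

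The steps were tested on simulated data. Noise was drawn separately for each gene, and missed loci were not simulated. In the data members of a list vary together, with an estimated correlation of 0.32 for the mitosis list. The simulation therefore cannot show how often camera with the preset correlation calls unchanged lists here. For each comparison 100 of the 12363 genes were changed 2-fold and 100 were changed 4-fold. For 4 against 0 µM, 41% of the 2-fold and 81% of the 4-fold changes were recovered, with 17 false calls. For 6 against 0 µM these were 43% and 86%, with 4 false calls, and for 6 against 4 µM they were 40% and 85%, with 5 false calls. The list test was simulated only for 6 against 0 µM, in 1 run with the mitosis list shifted by -0.5 at 6 µM. The shifted list was called, and 1 other list was called too.

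Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, a filter at 5 FPKM, median-of-ratios, quantile and TPM scaling, the replicate block alone and with median-of-ratios scaling, the highest transcript per gene, a prior without a trend, a fit of the compared doses only, a 2-fold threshold, and leaving out each library. The consensus exon value, alone or with the block, with median-of-ratios scaling or without replicate 1 at 0 µM, and a test of only the genes assembled in all 9 libraries were chosen after seeing the data. Agreement of the fold changes at the 2 doses was set against 100 simulations of unchanged groups that shared the control libraries. There the genes with the smallest p, as many as were called in the data, stood for the calls, a comparison added after the counts were seen. Exact permutation tests used scipy 1.17.1, where the smallest possible two-sided p for 3 against 3 is 0.1. Figures were drawn with matplotlib 3.10.9. Single-exon transcripts that lay inside a gene but outside its assembled exons, and transcripts outside genes, did not enter gene values.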

Results

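Transcript levels were measured in WM3248, a human melanoma cell line, 24 h after the cells received ARN22089 at 0, 4 or 6 µM, with 3 libraries at each dose. ARN22089 is a small molecule designed to keep GTPases of the CDC42 family, among them CDC42, RHOJ and RHOQ, from binding effectors such as the kinase PAK, and the libraries at 0 µM received only the vehicle. Each library was assembled separately, into between 26506 and 30798 transcripts, from which between 12135 and 12916 genes were named. The depth in reads is unknown. Relative to the median library it ran from 0.8 in replicate 3 at 4 µM to 1.34 in replicate 1 at 6 µM. Nothing in the descriptions says that the libraries of a dose came from separate cultures, so all p-values measure only the spread between these libraries, which may be technical. Levels are given as the summed FPKM of a gene's transcripts (mean ± SD, n = 3), differences as log2 differences of FPKM + 1 with their SE, adjusted p-values are those of limma or its camera test, and coordinates are in GRCh38.

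The genes of the GTPases that the compound was designed to act on did not pass the test at either dose. CDC42 (chromosome 1, 22052586 to 22092949) was at 117 ± 5.48 FPKM (SD, n = 3) at 0 µM, 111 ± 5.54 at 4 µM and 111 ± 5.2 at 6 µM. RHOJ (chromosome 14, 63204297 to 63293513) was at 23 ± 12.9, 18.9 ± 3.8 and 15.6 ± 0.562 FPKM, a log2 difference of -0.36 at 6 µM that was 0.05 with the consensus exon value. RHOQ (chromosome 2, 46542701 to 46581373) was at 25.2 ± 2.1, 27.1 ± 6.16 and 27 ± 2.34 FPKM. PAK1 (chromosome 11, 77322004 to 77474034), an effector kinase of CDC42, was at 18.6 ± 2.93, 12.3 ± 0.849 and 12.1 ± 0.715 FPKM, with a log2 difference of -0.57 ± 0.14 and an adjusted p of 0.103 at 6 µM. PAK2 (chromosome 3, 196739847 to 196832597) was at 21.4 ± 8.34, 19.2 ± 8.16 and 17.9 ± 6.66 FPKM. The list of CDC42 family genes and effectors, with 29 measured members, had a median log2 difference of -0.03 at 4 µM and 0.05 at 6 µM, and the camera test gave adjusted p-values of 0.81 and 0.75. No member of that list passed limma's test at either dose, and at an unadjusted p below 0.05 there were 2 lower members at 4 µM, and 3 higher and 2 lower at 6 µM.

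The comparison of 4 with 0 µM asks what the lower dose changed. TNFRSF14 (chromosome 1, 2555780 to 2577077), a receptor of the TNF receptor family, rose from 18.9 ± 5.27 to 69.4 ± 5.91 FPKM (SD, n = 3), a log2 difference of 1.86 ± 0.20 (adjusted p = 0.0201). ZNF557 (chromosome 19, 7069422 to 7086332), a zinc finger gene, rose from 3.11 ± 0.365 to 9.38 ± 0.322 FPKM, a log2 difference of 1.34 ± 0.14 (adjusted p = 0.0201). SPHK2 (chromosome 19, 48619327 to 48630633), which encodes a sphingosine kinase, was listed at 0 in the 3 libraries at 0 µM and at 12.3, 9.22 and 9.3 FPKM in those at 4 µM (adjusted p = 0.00151). NEK6 (chromosome 9, 124257944 to 124359342), a kinase that acts in mitosis, rose from 7.86 ± 1.06 to 26.7 ± 5.82 FPKM (adjusted p = 0.0201), but with the consensus exon value its log2 difference was 0.32 (adjusted p = 0.58).

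In all, 11 of 12363 genes passed limma's test at 4 µM, 10 higher and 1 lower, and 1339 had an unadjusted p below 0.05. The rule for named genes took 7 of the 11, all higher. Beside the 4 above, these were IMMP1L, POFUT4 and PYCARD-AS1, each listed at 0 in every library at 0 µM. IMMP1L (chromosome 11, 31432406 to 31509628) was at 4.77, 12.1 and 18.8 FPKM at 4 µM and POFUT4 (chromosome 10, 73772183 to 73780240) at 6.6, 10.7 and 7.7 FPKM. PYCARD-AS1 (chromosome 16, 31202106 to 31202928), an antisense RNA whose strand is uncertain here, was at 10.4, 17.8 and 10.2 FPKM. POFUT4 turned direction with the consensus exon value, to a log2 difference of -1 (adjusted p = 0.16). With the replicate number as a block 2 genes passed, and the adjusted p of SPHK2 and POFUT4 was then 0.027, that of TNFRSF14, ZNF557 and NEK6 0.089, that of PYCARD-AS1 0.084 and that of IMMP1L 0.14. The count of 11 became 25, 24 and 17 without replicate 1, 2 or 3 at 0 µM, and 7 and 6 without replicate 1 or 2 at 6 µM, which share the estimate of the spread. SPHK2 and POFUT4 passed with each of the 9 libraries left out in turn, NEK6 with 6, ZNF557 with 5, TNFRSF14 and PYCARD-AS1 with 4 and IMMP1L with 1. SPHK2 and POFUT4 stay at 0 in the controls whichever library is left out. Their calls therefore cannot tell a missed locus from an absent transcript.

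Genes of the cell division cycle were lower at 4 µM. All 34 measured members of the mitosis list had negative differences, with a median of -0.63. MKI67 (chromosome 10, 128096402 to 128126386), a marker of proliferating cells, was at 24.5 ± 5.34 FPKM at 0 µM and 13.1 ± 1.59 at 4 µM. KIF20A (chromosome 5, 138178689 to 138187704), a mitotic kinesin, was at 36.1 ± 3.02 and 21 ± 2.67. No member passed over all genes (18 lower at an unadjusted p below 0.05), and 12 fell when adjusted over the list alone. The list was called by camera (adjusted p = 1.3e-15; adjusted p = 0.25 with an estimated correlation). In the DNA replication list 32 of 34 members had negative differences, with a median of -0.41 (adjusted p = 9.5e-08; adjusted p = 0.40 with an estimated correlation). Its members CCNE2 (chromosome 8, 94880334 to 94895215), a cyclin of the G1/S transition, and CLSPN (chromosome 1, 35719890 to 35770094), a replication checkpoint adaptor, went from 28.6 ± 13 to 7.63 ± 1.98 FPKM and from 9.81 ± 3.65 to 3.94 ± 1.4 FPKM. The log2 difference of CCNE2 was -1.68 with the summed and -0.89 with the consensus exon value (adjusted p = 0.37 and 0.19). No replication gene passed, either over all genes or adjusted over the list alone, and 12 were lower at an unadjusted p below 0.05.

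Genes of cholesterol and fatty acid synthesis were higher at 4 µM, with positive differences in 30 of 31 measured members and a median of 0.74. FDPS (chromosome 1, 155308617 to 155320559), which makes farnesyl diphosphate, was at 213 ± 46.5 FPKM at 0 µM and 464 ± 33.4 at 4 µM. MVD (chromosome 16, 88651934 to 88663216), an enzyme of the mevalonate pathway, was at 24.3 ± 6.5 and 60 ± 14.4. No member passed over all genes (25 higher at an unadjusted p below 0.05), and 24 rose when adjusted over the list alone. The camera test called the list (adjusted p = 2.5e-17; adjusted p = 0.25 with an estimated correlation). Melanocyte differentiation genes had positive differences in 18 of 19 members, with a median of 0.62 (adjusted p = 1.6e-07; adjusted p = 0.34 with an estimated correlation). With each library at 4 µM set against its numbered control, their medians were 0.88, 0.38 and 0.4, in order of replicate number. For cholesterol synthesis genes these were 1.15, 0.6 and 0.38, so replicate 1 gave the largest difference in both lists. DCT (chromosome 13, 94437491 to 94479939), an enzyme of melanin synthesis, was at 91.2 ± 44.5 and 262 ± 18 FPKM. RAB38 (chromosome 11, 88113337 to 88175510), which acts in melanosome formation, was at 47.1 ± 9.52 and 73.6 ± 9.55. Over all genes 0 melanocyte genes passed, 9 were higher at an unadjusted p below 0.05, and 2 rose when adjusted over the list alone. The melanocyte regulators MITF (chromosome 3, 69739449 to 69968484) and SOX10 (chromosome 22, 37970633 to 37985847) did not pass, at 13.5 ± 4.86 and 15.4 ± 2.42 FPKM and at 125 ± 20.1 and 150 ± 8.83 FPKM.

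Further lists were called at 4 µM. Targets of YAP/TAZ and TEAD, transcription regulators that respond to the actin cytoskeleton, had negative differences in 13 of 18 members and a median of -0.45 (adjusted p = 0.0016; adjusted p = 0.25 with an estimated correlation). Of these 2 fell when adjusted over the list alone. AXL (chromosome 19, 41218935 to 41261918), a receptor kinase, was at 20.5 ± 7.51 and 9.61 ± 1.1 FPKM. AMOTL1 (chromosome 11, 94768208 to 94877093), a binding partner of YAP, was at 30.2 ± 1.13 and 21.2 ± 1.43. Its log2 difference was -0.50 with the summed value and -0.01 with the consensus exon value (adjusted p = 0.27 and 1). Lysosome and autophagy genes had a median of 0.21 and positive differences in 27 of 34 members (adjusted p = 0.0005; adjusted p = 0.40 with an estimated correlation). WIPI1 (chromosome 17, 68421426 to 68457506), an autophagy gene, was at 22.4 ± 6.1 and 45.3 ± 1.63 FPKM. A single lysosome gene rose when adjusted over the list alone. Targets of ATF4, the regulator of the integrated stress response, had a median of 0.23 (adjusted p = 0.0038), hypoxia and glycolysis genes 0.24 (adjusted p = 0.0038) and NRF2 targets 0.23 (adjusted p = 0.007). Positive differences were found in 23 of 26, 27 of 30 and 16 of 20 members. Each of these 3 lists had an adjusted p of 0.64 with an estimated correlation and no member that passed over all genes or adjusted over the list alone. At an unadjusted p below 0.05 they held 6, 3 and 5 higher members. The ATF4 call was lost without replicate 2 or 3 at 0 µM or replicate 1 at 4 µM (adjusted p = 0.076, 0.091 and 0.15). The hypoxia call was lost without replicate 1 at 0 µM or replicate 2 at 4 µM (0.075 and 0.067), and the NRF2 call without replicate 2 or 3 at 0 µM (0.21 and 0.18). NF-kB targets, with a median of 0.20, were not called (adjusted p = 0.093). That list was called without replicate 3 at 0 µM (adjusted p = 0.048), without replicate 3 at 4 µM (0.0031) and with the consensus exon value (0.014). With an estimated correlation its adjusted p was 0.74 with the summed and 0.53 with the consensus exon value.

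**Figure D1:**
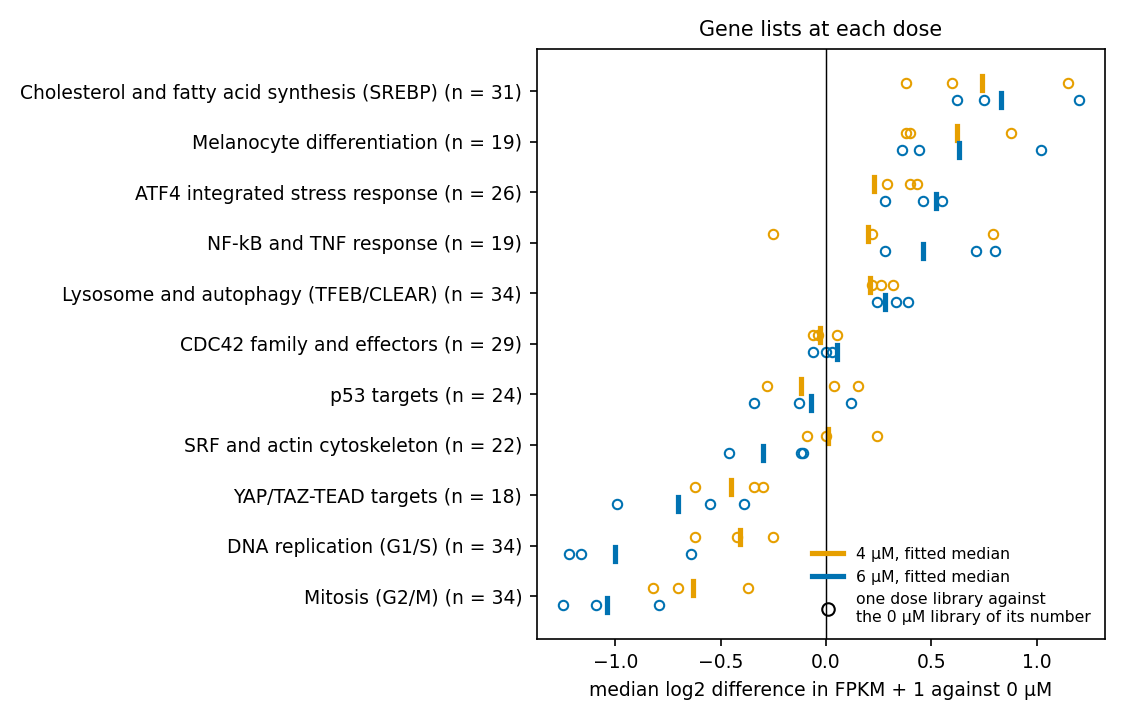
Median log2 difference in FPKM + 1 against 0 µM (horizontal axis) for 11 gene lists with their number of measured members (vertical axis). Bars stand for the fitted median at 4 µM (orange) and 6 µM (blue), and open circles for each library at that dose against the 0 µM library of the same replicate number. The mitosis bars lie at -0.63 and -1.04, the cholesterol synthesis bars at 0.74 and 0.83 and the CDC42 family bars at -0.03 and 0.05.

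The comparison of 6 with 0 µM asks what the higher dose changed. NFKBIA (chromosome 14, 35401516 to 35405177), the inhibitor that retains NF-kB in the cytoplasm, rose from 16.2 ± 4.65 to 90.7 ± 13.2 FPKM (SD, n = 3), a log2 difference of 2.44 ± 0.36. TNFAIP3 (chromosome 6, 137866476 to 137883308), which encodes another inhibitor of NF-kB signalling, rose from 3.27 ± 0.301 to 14.4 ± 2.45 FPKM, a difference of 1.84 ± 0.18. SAT1 (chromosome X, 23783144 to 23786073), the enzyme that starts polyamine breakdown, rose from 64.9 ± 3.04 to 272 ± 51.9 FPKM (2.03 ± 0.18), and TNFRSF14 rose to 80.7 ± 1.22 FPKM (2.08 ± 0.20). CCN1 (chromosome 1, 85580768 to 85583701), a secreted matrix protein and target of YAP, fell from 27.1 ± 5.63 to 6.93 ± 2.48 FPKM, a log2 difference of -1.86 ± 0.28. MCM5 (chromosome 22, 35400075 to 35424509), a subunit of the replicative helicase, fell from 42.8 ± 1.34 to 17.9 ± 5.28 FPKM, a difference of -1.25 ± 0.20. The adjusted p was 0.0464 for NFKBIA and CCN1, 0.0097 for TNFAIP3, 0.00819 for SAT1, 0.00938 for TNFRSF14 and 0.0497 for MCM5.

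Further genes were named by the size of their rise at 6 µM. MVD rose to 75.3 ± 11.7 FPKM (log2 difference 1.62 ± 0.25), and RIPK4 (chromosome 21, 41739367 to 41767152), a kinase of the RIP family, from 9.84 ± 1.38 to 29 ± 3.54 FPKM (1.47 ± 0.20). APOC1 (chromosome 19, 44914253 to 44919349), an apolipoprotein, rose from 11 ± 0.765 to 31.7 ± 4.79 FPKM (1.44 ± 0.23). SPHK2 and POFUT4 were listed at 0 in every library at 0 µM and at 5.48, 7.82 and 9.05 FPKM and 6.43, 10.4 and 8.23 FPKM at 6 µM. NCKAP5 (chromosome 2, 132671798 to 133674829) rose from 3.03 ± 1.14 to 12 ± 0.974 FPKM, but by 0.10 on the log2 scale with the consensus exon value (adjusted p = 0.79), and POFUT4 turned to -1 there (adjusted p = 0.035). ATAD2 (chromosome 8, 123319817 to 123416353), a bromodomain ATPase, fell from 27.2 ± 9.25 to 6.27 ± 1.23 FPKM (-1.91 ± 0.28), and SERPIND1 (chromosome 22, 20779775 to 20787720), a thrombin inhibitor, from 22 ± 8.2 to 5.66 ± 0.537 FPKM (-1.73 ± 0.28). DEPDC1B (chromosome 5, 60596991 to 60700182) fell from 25.3 ± 0.999 to 8.09 ± 2.51 FPKM (-1.57 ± 0.23), and SEMA7A (chromosome 15, 74409296 to 74434004), a semaphorin, from 6.79 ± 0.589 to 2.24 ± 0.423 FPKM (-1.27 ± 0.20). CDCA2 (chromosome 8, 25458992 to 25511391), a regulator of chromosome structure in mitosis, fell from 12.7 ± 2.57 to 4.65 ± 0.701 FPKM (-1.27 ± 0.19). DEPDC1B differed by -0.88 with the consensus exon value (adjusted p = 0.038). HS2ST1 (chromosome 1, 86914666 to 87110116) and SHLD1 (chromosome 20, 5750285 to 5863899) fell with the summed value, with log2 differences of -1.39 ± 0.21 and -1.29 ± 0.17. The consensus exon value gave them -0.32 (adjusted p = 0.10) and -0.30 (adjusted p = 0.21). DHRS13 (chromosome 17, 28897773 to 28903093) was at 8.8, 11 and 10.8 FPKM at 0 µM and listed at 0 in the 3 libraries at 6 µM, but turned to 0.30 with the consensus exon value (adjusted p = 0.42).

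In all, 54 genes passed limma's test at 6 µM, 33 higher and 21 lower, and 2189 had an unadjusted p below 0.05. With the consensus exon value, chosen after seeing the data, 536 genes passed, 213 higher and 323 lower, 39 of them among the 54. Rescaling to TPM left 15 higher and 1 lower. In the 20 genes named by the size of their change, the adjusted p lay between 0.000167 for DHRS13 and 0.0497. With the replicate number as a block 4 genes passed: POFUT4 (adjusted p = 0.016), SPHK2 and SAT1 (0.037) and DHRS13 (0.005), and the other named genes had adjusted p-values between 0.053 and 0.074. The count of 54 became 32 and 33 without replicate 2 or 3 at 0 µM, 23, 15 and 31 without replicate 1, 2 or 3 at 4 µM, and 16 without replicate 1 or replicate 2 at 6 µM. POFUT4, SPHK2, TNFRSF14, SAT1, TNFAIP3 and DHRS13 passed with each library left out in turn, and the other 14 lost the call in at least 6 of the 9 cases. POFUT4, SPHK2 and DHRS13 were listed at 0 in every library of a dose, whichever library is left out. For them neither the block nor leaving out a library can tell a missed locus from an absent transcript. POFUT4 and DHRS13 turned direction with the consensus exon value.

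**Figure D2:**
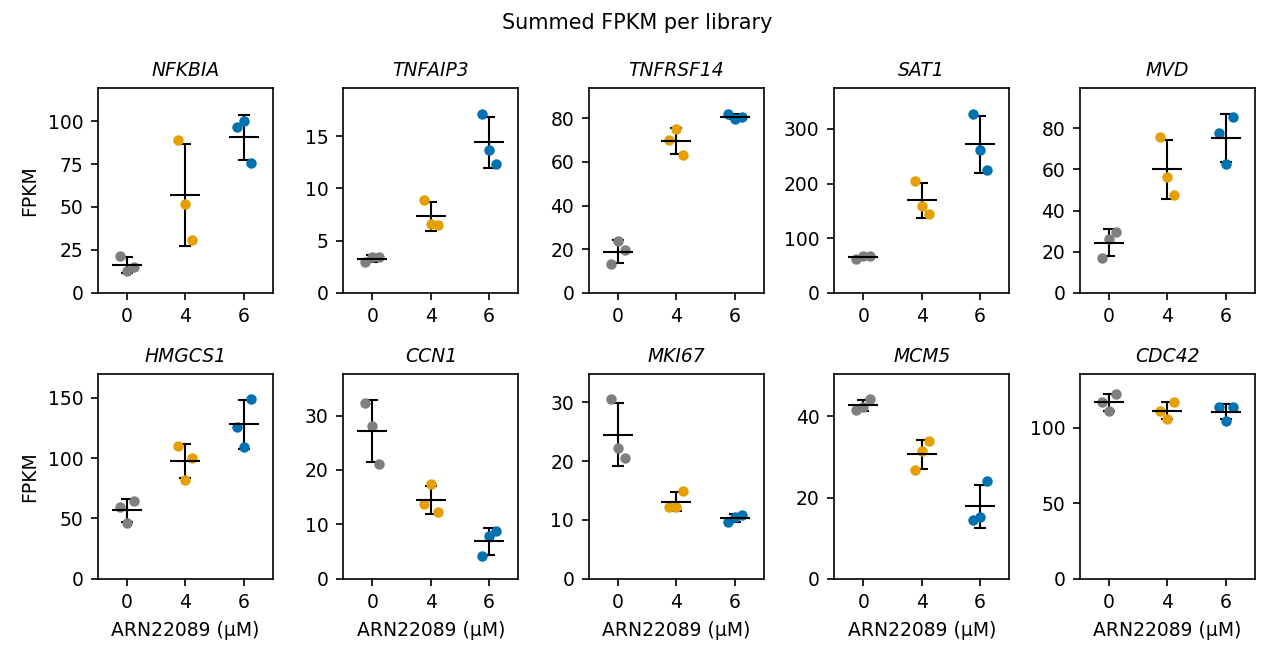
Summed FPKM (vertical axes, linear from 0) of 10 genes against the dose of ARN22089 in µM (horizontal axes); each point is 1 library, the wide bar is the mean and the error bars are the SD of 3 libraries. TNFRSF14 lies at 18.9, 69.4 and 80.7 FPKM at 0, 4 and 6 µM, MCM5 at 42.8, 30.7 and 17.9, and CDC42 at 117, 111 and 111.

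The division cycle lists were again lower at 6 µM. All 34 mitosis genes had negative differences, with a median of -1.04, and 4 fell over all genes. MKI67 fell to 10.3 ± 0.626 FPKM (-1.15 ± 0.17), and AURKB (chromosome 17, 8204746 to 8210645), a kinase of the chromosomal passenger complex, from 71.3 ± 9.71 to 33.2 ± 6.26 FPKM (-1.09 ± 0.17). NUSAP1 (chromosome 15, 41332719 to 41380162), a spindle protein, fell from 76 ± 5.5 to 34.2 ± 6.76 FPKM (-1.14 ± 0.18), and KIF20A, to 18 ± 2.8 FPKM (-0.97 ± 0.16). Their adjusted p was 0.0464 for MKI67, AURKB and NUSAP1 and 0.0497 for KIF20A, and between 0.053 and 0.074 with the block. With each of the 9 libraries left out in turn, KIF20A lost the call in 9 cases and MKI67, AURKB and NUSAP1 in 8 each. Adjusted over the list alone, 31 mitosis genes fell, and camera gave an adjusted p of 2.4e-22 for the list (adjusted p = 0.12 with an estimated correlation). All 34 replication genes also had negative differences, with a median of -1 (adjusted p = 4.4e-18; adjusted p = 0.13 with an estimated correlation). MCM5 fell over all genes, 29 fell when adjusted over the list alone, and CCNE2 and CLSPN, which did not pass, were at 7.12 ± 5.78 and 2.99 ± 0.661 FPKM. With the consensus exon value 27 mitosis and 19 replication genes fell over all genes, CCNE2 among them (adjusted p = 0.026).

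YAP/TAZ and TEAD targets had negative differences in 16 of 18 members at 6 µM and a median of -0.70 (adjusted p = 3.9e-06; adjusted p = 0.12 with an estimated correlation). CCN1 fell over all genes, and 9 members fell when adjusted over the list alone. Genes of SRF and the actin cytoskeleton had negative differences in 16 of 22 members and a median of -0.30 (adjusted p = 0.049; adjusted p = 0.49 with an estimated correlation). No member passed either adjustment, and 4 were lower at an unadjusted p below 0.05. Among them CNN2 (chromosome 19, 1026323 to 1039098), a calponin, was at 57.2 ± 19.1 and 30.1 ± 4.82 FPKM and TPM1 (chromosome 15, 63042622 to 63071309), a tropomyosin, at 116 ± 29.4 and 71.7 ± 17. CNN2 differed by -0.86 with the summed and by -1.30 with the consensus exon value (adjusted p = 0.14 and 0.16). The SRF call was lost without 7 of the 9 libraries. These were replicates 2 and 3 at 0 µM (adjusted p = 0.17 and 0.15), replicates 1, 2 and 3 at 4 µM (0.059, 0.055 and 0.052) and replicates 1 and 2 at 6 µM (0.081 and 0.26). It was also lost with fry (adjusted p = 0.16), a pseudocount of 0.1, a filter at 5 FPKM and median-of-ratios or TPM scaling. The highest transcript per gene and a fit of the compared doses alone lost it too. Endoplasmic reticulum chaperones had negative differences in 15 of 19 members, with a median of -0.37 (adjusted p = 0.0047; adjusted p = 0.25 with an estimated correlation). Of these 4 fell when adjusted over the list alone. HSPA5 (chromosome 9, 125236370 to 125241475), the main chaperone of that compartment, was at 499 ± 80.2 and 307 ± 14.9 FPKM, and MANF (chromosome 3, 51385256 to 51389283) at 139 ± 0.748 and 89.1 ± 6.66. Neither passed over all genes, and 7 of the list were lower and 1 higher at an unadjusted p below 0.05.

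Cholesterol and fatty acid synthesis genes had positive differences in 29 of 31 members at 6 µM and a median of 0.83 (adjusted p = 4.8e-17; adjusted p = 0.12 with an estimated correlation). MVD and HMGCS1 (chromosome 5, 43289391 to 43313551), the synthase that makes HMG-CoA, rose over all genes, HMGCS1 from 56.7 ± 9.53 to 128 ± 20.1 FPKM (1.16 ± 0.19, adjusted p = 0.0497; 0.053 with the block). Both MVD and HMGCS1 lost the call with each of the 9 libraries left out in turn. Adjusted over the list alone, 25 members rose. FDPS was at 440 ± 41.5 FPKM (adjusted p = 0.0534) and EBP (chromosome X, 48521636 to 48528800), a sterol isomerase, at 45.6 ± 5.71 at 0 µM and 81.7 ± 12 at 6 µM. With the consensus exon value 16 members rose over all genes. NF-kB and TNF response genes had positive differences in 17 of 19 members and a median of 0.46 (adjusted p = 2.1e-05; adjusted p = 0.25 with an estimated correlation). NFKBIA and TNFAIP3 passed over all genes, and 5 members rose when adjusted over the list alone. Melanocyte differentiation genes had positive differences in 18 of 19 members and a median of 0.63 (adjusted p = 6.3e-08; adjusted p = 0.25 with an estimated correlation). Of these 6 rose when adjusted over the list alone and none over all genes, where 7 were higher at an unadjusted p below 0.05, and DCT was at 291 ± 73.8 FPKM (adjusted p = 0.0614). MITF was at 16.3 ± 0.608 FPKM and SOX10 at 151 ± 6.87, and neither passed. With each library at 6 µM set against its numbered control, melanocyte genes had medians of 1.02, 0.36 and 0.44, in order of replicate number. Cholesterol synthesis genes had 1.2, 0.75 and 0.62.

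The remaining called lists at 6 µM were higher. ATF4 targets had positive differences in 20 of 26 members and a median of 0.52 (adjusted p = 1e-04; adjusted p = 0.36 with an estimated correlation), and 7 rose when adjusted over the list alone. NUPR1 (chromosome 16, 28537357 to 28539100), a stress-induced chromatin protein, was at 1.41 ± 1.34 and 17.7 ± 8.17 FPKM, and SLC3A2 (chromosome 11, 62856009 to 62888880), a subunit of amino acid transporters, at 145 ± 26.9 and 231 ± 22. Lysosome and autophagy genes had a median of 0.28, with 26 of 34 positive (adjusted p = 0.00022; adjusted p = 0.25 with an estimated correlation). In that list WIPI1 was at 54.9 ± 9.13 FPKM (adjusted p = 0.0509) and NPC2 (chromosome 14, 74479987 to 74493594), a lysosomal cholesterol carrier, at 166 ± 32.3 and 317 ± 77.1. Hypoxia and glycolysis genes had a median of 0.26, with 22 of 30 positive (adjusted p = 0.0019; adjusted p = 0.49 with an estimated correlation). MXI1 (chromosome 10, 110207913 to 110287341), a partner of MAX, was at 14.5 ± 2.77 and 32.3 ± 5.44 FPKM. NRF2 targets had a median of 0.29, with 15 of 20 positive (adjusted p = 0.0026; adjusted p = 0.45 with an estimated correlation). PIR (chromosome X, 15384811 to 15493711) was at 39.1 ± 4.99 and 94.1 ± 23.6 FPKM. Ribosomal protein genes had a median of 0.16, with 29 of 43 positive (adjusted p = 0.015; adjusted p = 0.64 with an estimated correlation). RPL30 (chromosome 8, 98041717 to 98047307), which had the smallest p in that list, was at 647 ± 407 and 2310 ± 188 FPKM (limma adjusted p = 0.061). RPL10A (chromosome 6, 35468131 to 35470859) was at 362 ± 4.55 and 537 ± 73.4 FPKM. None of the members of these 5 lists passed over all genes. Adjusted over the list alone, 1 lysosome, 1 hypoxia, 3 NRF2 and 1 ribosomal gene rose, and at an unadjusted p below 0.05 the 5 lists held 8, 9, 6, 4 and 4 higher members. The hypoxia call was lost without replicate 2 at 6 µM (adjusted p = 0.078) and the NRF2 call without replicate 2 at 0 µM (0.071). The ribosomal call was lost without replicate 2 at 0 µM (0.33) or replicate 2 at 6 µM (0.064). The hypoxia call was also lost with the highest transcript per gene, and the ribosomal call with quantile scaling.

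The libraries at 6 µM also differed in transcripts that entered no gene value. Single-exon transcripts inside genes but outside their assembled exons took 0.63 ± 0.068% of FPKM times length at 6 µM and 0.46 ± 0.015% at 0 µM (SD, n = 3; exact permutation p = 0.1, two-sided, the smallest that 3 against 3 allows). The mitochondrial genome was assembled as 1 transcript in all libraries at 0 and 4 µM but in only 1 of 3 at 6 µM. Markers of other cell types did not pass over all genes at either dose. Of 8 fibroblast markers 6 were assembled, and LUM (chromosome 12, 91103669 to 91111594) and FAP (chromosome 2, 162170685 to 162243603) were the highest, named like KRT18 after their values were seen. LUM was at 15.8 ± 7.89 FPKM at 0 µM and 15.7 ± 6.16 at 6 µM and FAP at 16.1 ± 4.99 and 19.2 ± 2.99 (SD, n = 3). Of 11 keratinocyte and epithelial markers 4 were assembled, with KRT18 (chromosome 12, 52947795 to 52952905) at 76.2 ± 62.5 and 52.9 ± 4.43 FPKM, and of 12 blood and endothelial markers 4 were assembled. CD68 (chromosome 17, 7579278 to 7581855) was at 142 FPKM in replicate 3 at 4 µM and at 0 in the 8 other libraries. Adjusted over the list alone with the consensus exon value, LYZ (chromosome 12, 69348335 to 69354193) fell at 4 and 6 µM and KRT14 (chromosome 17, 41582321 to 41584979) at 6 µM (log2 differences -0.40, -0.36 and -1.35). These 3 genes were also named after their values were seen.

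The comparison of 6 with 4 µM asks whether the step between the doses changed further genes. NF-kB targets were higher as a group at 6 µM, with positive differences in 15 of 19 members. TNFAIP3 was at 7.32 ± 1.38 and 14.4 ± 2.45 FPKM (SD, n = 3) and NFKBIA at 57 ± 29.7 and 90.7 ± 13.2 at 4 and 6 µM. Replication genes were lower in 34 of 34 members, with a median of -0.50, and mitosis genes in 33 of 34, with a median of -0.41, and MCM5 was at 30.7 ± 3.6 and 17.9 ± 5.28 FPKM. The camera test gave adjusted p-values of 7.4e-14 for replication, 1.8e-11 for mitosis and 3.2e-06 for NF-kB targets, whose median was 0.46 (adjusted p = 0.42 with an estimated correlation for each). YAP/TAZ and TEAD targets were lower, with a median of -0.26 (adjusted p = 0.00047; adjusted p = 0.42 with an estimated correlation), and CCN1 was at 14.5 ± 2.63 and 6.93 ± 2.48 FPKM. No list member passed over all genes, and adjusted over the list alone 1 NF-kB gene, TNFAIP3, rose. Of the blood and endothelial markers, too few for camera, PECAM1 (chromosome 17, 64385286 to 64391473), named after its values were seen, fell adjusted over the list alone (4.99 ± 1.87 and 1.9 ± 0.31 FPKM). Its log2 difference was -1 with the summed value and 0.01 with the consensus exon value. At an unadjusted p below 0.05 there were 12 lower replication genes, 11 lower mitosis genes, 3 higher NF-kB genes and 4 lower YAP targets.

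A further 4 lists were called between the doses. SRF and actin genes had a median of -0.22 (adjusted p = 0.012; adjusted p = 0.51 with an estimated correlation) and endoplasmic reticulum chaperones -0.28 (adjusted p = 0.023; adjusted p = 0.45 with an estimated correlation). In these lists 18 of 22 and 16 of 19 members were negative. Cholesterol synthesis genes had a median of 0.12 (adjusted p = 0.012; adjusted p = 0.69 with an estimated correlation) and ATF4 targets 0.13 (adjusted p = 0.025; adjusted p = 0.74 with an estimated correlation). Here 25 of 31 and 21 of 26 members were positive. Each of these calls was lost when single libraries were left out. The SRF call was lost without replicate 1 at 4 µM or 2 at 6 µM (adjusted p = 0.068 and 0.24), and the chaperone call without replicate 2 at 4 µM or 3 at 6 µM (0.12 and 0.094). The cholesterol synthesis call was lost without replicate 3 at 4 µM or 1 at 6 µM (0.28 and 0.063), and the ATF4 call without replicate 2 or 3 at 4 µM or 1 at 6 µM (0.27, 0.24 and 0.54). Without a filter on low values the cholesterol and ATF4 calls were lost (0.07 and 0.079), with the highest transcript per gene those of the SRF, chaperone and YAP lists (0.057, 0.15 and 0.098), and with quantile scaling that of the chaperones (0.067).

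Between the doses 7 genes passed limma's test, 4 higher and 3 lower, and 579 had an unadjusted p below 0.05. SPTAN1 (chromosome 9, 128552595 to 128633757), a spectrin, was higher with the summed value (22.3 ± 0.776 and 57.2 ± 7.18 FPKM, adjusted p = 0.021) but turned to -0.32 with the consensus exon value. SMARCA4 (chromosome 19, 10960999 to 11064147), a chromatin remodelling ATPase, fell by 1.14 ± 0.14 on the log2 scale with the summed value (adjusted p = 0.049) and differed by -0.36 with the other. DHRS13 was at 11.3, 14 and 11.7 FPKM at 4 µM and listed at 0 at 6 µM (adjusted p = 9.5e-05; log2 difference 0.10 with the consensus exon value). IMMP1L was at 4.77, 12.1 and 18.8 FPKM and listed at 0 (adjusted p = 0.049). With the block 1 gene passed, and with the consensus exon value 3, of which 2 were among the 7. The count became 2 without replicate 2 or replicate 3 at 0 µM, and 12 and 13 without replicate 2 or 3 at 6 µM. With each of the 9 libraries left out in turn, SMARCA4 lost the call in 9 cases, IMMP1L in 8 and SPTAN1 in 5. DHRS13 kept it each time, but its values of 0 at 6 µM stay whichever library is left out.

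The size of the list differences depended on the scaling. Rescaling to TPM left the median of all genes at 0.32 at 4 µM and 0.24 at 6 µM. At 4 µM the list medians were then -0.29 for mitosis, -0.07 for replication, -0.12 for YAP, 1.1 for cholesterol synthesis and 0.94 for melanocyte genes. They were 0.56 for lysosome, 0.58 for ATF4, 0.59 for hypoxia and 0.58 for NRF2 genes. At 6 µM they were -0.76 for mitosis, -0.75 for replication, -0.42 for YAP, -0.02 for SRF and -0.07 for chaperone genes. The higher lists at 6 µM had 1.13 for cholesterol synthesis, 0.93 for melanocyte, 0.75 for NF-kB, 0.82 for ATF4, 0.57 for lysosome, 0.56 for hypoxia, 0.59 for NRF2 and 0.46 for ribosomal genes. Camera sets a list against the other genes, and of the calls against 0 µM only that of SRF genes was lost with TPM (adjusted p = 0.13). Between the doses cholesterol synthesis genes had 0.06 and all calls were kept. Quantile scaling gave medians of 0.14 for NRF2 genes at 4 µM and 0.04 for ribosomal genes at 6 µM.

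The fold changes at the 2 doses were also set against each other. Of the 54 genes called at 6 µM, 50 had the same sign at 4 µM and 47 of these were smaller there, and 8 genes were called higher at both doses and 0 lower. Simulations of unchanged groups against the same control libraries gave means of 49.1 and 44.5 for the first counts and of 2.8 and 0.3 for the shared genes. They held no loci missed by the assembly, and their noise was drawn separately for each gene. In the data genes vary together, so the simulated means do not show how far such values range in unchanged groups. Among the genes shared as higher, SPHK2, POFUT4 and IGF1 were listed at 0 in every control library. A locus missed in all controls would add such a gene, so the simulated 2.8 may be too low. Lists drawn independently would share 0.027 and 0.002 genes. Across genes, which are not independent replicates, Pearson's r between the fold changes was 0.671, where the 100 simulations gave 0.5, and the covariance was 0.2365 against a simulated 0.1161, a difference of 0.1204. The counts with the consensus exon value were 534 of 536 genes with the same sign and 512 of these smaller at 4 µM, where simulations gave 469.7 and 404. There 7 genes were shared as higher and 0 as lower, against a simulated 4.4 and 1.2 and against 0.141 and 0.053 for independent lists, and the covariance was 0.1799 against 0.0685. The 3 control libraries do not give 2 sets of at least 2, so they could not be split. The simulated groups shared their controls too. The simulated counts and covariance therefore hold the part due to sharing, which the values for independent lists do not. A deviation of a control library common to many genes was not simulated, so part of the excess may still come from the shared controls.

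Several lists were not called in any comparison. At 4 and 6 µM against 0 µM the adjusted p was 0.57 and 0.53 for p53 targets, 0.47 and 0.61 for the BCL2 family, 0.54 and 0.53 for MAPK output, 0.47 and 0.40 for interferon response, and 0.91 and 0.89 for extracellular matrix. It was 0.34 and 0.53 for heat shock, 0.22 and 0.16 for oxidative phosphorylation, 0.47 and 0.091 for undifferentiated melanoma genes, 0.57 and 0.98 for fibroblast markers and 0.47 and 0.53 for replication-dependent histones. Between the doses the adjusted p of the same lists was 0.79, 0.91, 0.13, 0.78, 0.92, 0.79, 0.79, 0.17, 0.62 and 0.95 in that order. SRF genes, chaperones and ribosomal proteins were not called at 4 µM (adjusted p = 0.91, 0.17 and 0.30), nor were melanocyte, lysosome, hypoxia, ribosomal and NRF2 genes between the doses (0.17, 0.34, 0.34, 0.063 and 0.34).

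Some of these lists were called under other settings. Undifferentiated melanoma genes were called lower at 6 µM with the consensus exon value (adjusted p = 0.028), with no filter (0.027) and without replicate 1 at 0 µM (0.018). They were also called lower between the doses with the consensus exon value (0.035). Camera with an estimated correlation gave 0.19 and 0.24 with that value at 6 µM and between the doses. Without replicate 1 at 0 µM, interferon response (adjusted p = 0.037 and 0.04) and oxidative phosphorylation (0.00092 and 0.0033) were called at both doses, and ribosomal proteins (0.0038) and chaperones (0.0037) at 4 µM. Oxidative phosphorylation was also called with TPM scaling (0.044 and 0.037) and, at 4 µM, without replicate 1 at 4 µM (0.032), chaperones at 4 µM with quantile scaling (0.035), and ribosomal proteins at 4 µM without replicate 3 at 4 µM (0.042). Between the doses, ribosomal proteins were called without replicate 1 or 2 at 0 µM (0.037 and 0.047), replicate 2 at 4 µM (0.0028) or replicate 3 at 6 µM (0.012). MAPK output was called there without replicate 1 at 4 µM (0.03) or replicate 3 at 6 µM (0.027), and melanocyte genes without replicate 3 at 6 µM (0.035). Hypoxia genes were called without replicate 1 at 6 µM (0.01). Ribosomal proteins were called there with a filter at 5 FPKM (0.035), a fit of the compared doses alone (0.024) and the consensus exon value (0.016), with which melanocyte genes were called too (0.045). With the consensus exon value and an estimated correlation, both lists had an adjusted p of 0.69 between the doses. In lists that were not called, the median, the mean and the test differed in sign for SRF, MAPK output and extracellular matrix at 4 µM and for extracellular matrix and fibroblast markers at 6 µM. They also did so between the doses for the CDC42 family, interferon response, extracellular matrix, heat shock, oxidative phosphorylation and histones.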

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

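In this part the tests of the division cycle genes, of genomic DNA and of splits with the consensus exon value were chosen only after the result was seen, and those of depth, of genes listed at 0 and of splits with the summed value before. Single-exon transcripts inside genes but outside assembled exons, which entered no gene value, took a larger share of FPKM times length at 6 µM, 0.63 ± 0.068%, than in the control libraries at 0 µM, 0.46 ± 0.015% (SD, n = 3; exact permutation p = 0.1, the smallest possible). Single-exon transcripts outside genes, also unused and with the mitochondrial genome left out, took 0.493 ± 0.039% at 6 µM and 0.366 ± 0.02% at 0 µM (exact permutation p = 0.1). Both stood out as signals above the control libraries in data that no comparison uses.

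The share inside genes was weighed against depth and genomic DNA. Depth alone is argued against, since among such transcripts of at least 2 FPKM the lowest library at 6 µM was still 1.21 times the highest at 0 µM (0.315% and 0.261%). Under that cut the libraries at 4 µM also lay above those at 0 µM, at 0.282% to 0.299% (exact permutation p = 0.1, mean ratio 1.13, and 1.46 at 6 µM), while without it the mean at 4 µM was 0.98 times that at 0 µM. Genomic DNA may contribute and cannot be told apart from a rise of unspliced RNA, because the share outside genes was 1.35 times that at 0 µM, close to the 1.37 times inside genes but not above it. An effect of the 6 µM treatment on splicing or RNA decay stays open and was not tested.

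The lower mitosis and replication genes at 6 µM had a median log2 difference of -1.02 over both lists. Loci split or named differently by the assembly as the whole cause are argued against by the consensus exon value, with which the median was -1.04 (SD of members 0.29). That value cannot restore a locus missed in a library. Missed loci as the whole cause are argued against by the 67 of 68 members assembled in all 9 libraries, whose median was -1.02 (SD of members 0.35). A shift of all genes as the whole cause is argued against by median-of-ratios rescaling, after which it was -0.99 (SD of members 0.35), though TPM scaling left -0.76 for mitosis and -0.75 for replication. The same libraries had the larger single-exon shares given above, and the replicate numbers gave -1.09, -1.25 and -0.79 for the mitosis list when each library at 6 µM was set against its numbered control. A response of the cells to the compound is a candidate explanation that stays open, on the same data that showed the pattern.

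In the comparisons with 0 µM, 15 genes were listed at 0 in every library of 1 dose and at 5 FPKM or more in every library of the other. Of these 26.7%, or 4, still had at least 77.6% of the other dose's consensus exon value, and the rest at most 0.9%. For HLA-DRB5, 1 of the 4, that value was 30400 at 0 µM, where it was listed at 0, and 270 at 4 µM. So large a gap is no sign of the same transcript kept under another name. A locus that was joined or named differently may explain the others, POFUT4, DHRS13 and PPT2. Over all 15 this and absence of the transcript cannot be told apart. Genes at 0 in exactly 3 libraries and at 5 FPKM or more in the other 6 were also counted. The sets at 0, 4 and 6 µM held 2, 0 and 1 such genes, a mean of 1. The 81 sets of 3 libraries of mixed doses had a mean of 0.41 and at most 3, and 32.1% of them reached 1. Such zeros thus also fell on mixed sets. Counts this small, under a stricter rule, cannot say how many of the 15 are loci missed by chance. Absence of the transcript at a dose, as listed for SPHK2, stays open.

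Other splits of the 6 libraries of a comparison were counted, 10 in each. With the summed value the gene count at 4 µM was 11 and the highest other 5, at 6 µM 54 and 5, and between the doses 7 and 6, with 1 of 10 splits, the real one, giving as many each time. Among splits that part as many replicate pairs, the highest others were 2, 3 and 6. With the consensus exon value the counts were 10 and 9 at 4 µM, 536 and 4 at 6 µM, and 3 and 9 between the doses, where 6 of 10 splits gave at least as many genes as the real one. The list counts were 9, 13 and 8 with highest others of 10, 15 and 11, and 2, 2 and 3 of the 10 splits gave as many lists. With 10 splits the share is never under 0.1, so the splits are too few to say more. In all 3 comparisons the highest list count came from 1 of the 2 splits that put both libraries of replicate number 1 on one side and both of number 3 on the other. The other of these splits gave only 5, 4 and 1 lists, so the high counts do not follow the replicate number alone. With that number as a block the list counts were 9, 13 and 8. Among splits that part as many pairs the highest other list counts were 5, 9 and 3. The real list counts with the consensus exon value were 10, 14 and 11 and the highest others 11, 14 and 11. At both doses the real median was the largest of the 10 splits for the mitosis, replication, cholesterol, melanocyte and YAP lists, as in -1.04 against 0.54 in size for mitosis at 6 µM. Their real unadjusted camera p was also the smallest, though for melanocyte genes at 6 µM only by 1e-08 against 3.1e-08. Lysosome genes at 6 µM also had the largest median (0.28 and 0.23) and the smallest camera p (7.4e-05 and 0.00051) in the real split. For ATF4 genes (0.52 and 0.46) and chaperones (-0.37 and 0.25) at 6 µM the real median was the largest too. There another split gave the smaller camera p, 1.3e-07 against 3e-05 and 0.00086 against 0.0022. Real and largest other medians, the latter as sizes, were 0.23 and 0.44 for ATF4, 0.24 and 0.33 for hypoxia, 0.21 and 0.25 for lysosome and 0.23 and 0.50 for NRF2 genes at 4 µM. At 6 µM they were 0.46 and 0.64 for NF-kB, 0.26 and 0.37 for hypoxia, 0.29 and 0.48 for NRF2, 0.16 and 0.32 for ribosomal and -0.30 and 0.31 for SRF genes. Between the doses they were -0.50 and 0.53 for replication, 0.46 and 0.56 for NF-kB, -0.26 and 0.28 for YAP, -0.22 and 0.26 for SRF, 0.12 and 0.13 for cholesterol and 0.13 and 0.36 for ATF4 genes. Among the lists called between the doses, only mitosis (-0.41 and 0.36) and chaperones (-0.28 and 0.16) had their largest median in the real split.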

How the results depend on the processing

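The consensus exon value, its combinations and the restriction to genes assembled in all libraries were chosen after seeing the data, and the other alternatives before. Over all alternatives the results of named genes, called or not, had the same direction and side of the threshold 1719 times. They lost a call 380 times, gained one 50 times and turned 21 times, and for lists these were 1757, 93, 55 and 3. A result that stayed uncalled counts as the same, so these numbers are not the share of calls kept. Only 7 named genes at 4 µM, 20 by size and 5 more by list at 6 µM, and 4 between the doses were called. For lists these were 9, 13 and 8 of 24. With the replicate number as a block, which pairs the libraries, 2, 4 and 1 genes passed at 4 and 6 µM against 0 µM and between the doses (11, 54 and 7 without it), or 2, 3 and 1 with median-of-ratios scaling as well. The block ended the call in 29 of 84 results of named genes, of which only the 7, 20, 5 and 4 given above had a call to lose. It changed no other call, including all 72 results of lists. Depth in reads is unknown, so the limit it sets for low genes could not be given.

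Gene counts in the same order of comparisons moved as follows, and the cause was not tested except where stated. A filter at 5 FPKM gave 7 at 4 µM and 2 between the doses, with fewer genes tested. Median-of-ratios scaling gave 3 between the doses, and TPM scaling gave 16 at 6 µM and 4 between the doses. The highest transcript per gene gave 6 at 4 µM and 34 at 6 µM, a prior without a trend 21 at 6 µM, and a fit of the compared doses, which has fewer libraries, 17 at 6 µM and 4 between the doses. The consensus exon value gave 536 at 6 µM and 3 between the doses, with the block 5, 697 and 0 (817 at an unadjusted p below 0.05 by limma), with median-of-ratios scaling 581 at 6 µM and 3 between the doses, and without replicate 1 at 0 µM 23, 324 and 3. Only genes assembled in all 9 libraries gave 3, 175 and 1. List counts of 9, 13 and 8 became 0, 0 and 0 with camera and an estimated correlation (3, 4 and 2 at an unadjusted p below 0.05), 3, 8 and 0 with fry (6, 9 and 5), 5 between the doses with the highest transcript per gene, and 15 at 4 µM with the consensus exon value without replicate 1 at 0 µM. At 4 µM fry kept only the mitosis, cholesterol and YAP calls (adjusted p = 0.046, 0.035 and 0.046). At 6 µM it lost the SRF, ATF4, lysosome, hypoxia, ribosomal and NRF2 calls (0.16, 0.14, 0.051, 0.25, 0.41 and 0.24). There it called undifferentiated melanoma genes lower (0.014). The correlation of the fold changes at the 2 doses, 0.671, was 0.736 with the consensus exon value, alone, with the block or with median-of-ratios scaling, 0.754 with it without replicate 1 at 0 µM, and 0.752 for genes assembled in all libraries.

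Leaving out each library in turn gave 6 genes (without replicate 2 at 6 µM) to 25 (without replicate 1 at 0 µM) at 4 µM, 15 (without replicate 2 at 4 µM) to 78 (without replicate 1 at 0 µM) at 6 µM and 2 (without replicate 2 or replicate 3 at 0 µM) to 13 (without replicate 3 at 6 µM) between the doses. Lists ranged from 7 to 13, 10 to 16 and 6 to 10, and the correlation from 0.6 to 0.734.

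With the consensus exon value some directions turned, which its construction explains where a locus was joined or named differently. POFUT4 had log2 differences of -1 at 4 µM and -1 at 6 µM, the same with the block, -0.86 and -0.85 without replicate 1 at 0 µM, and -0.99 and -0.94 with median-of-ratios scaling. In that order of settings DHRS13 had 0.3, 0.3, 0.21 and 0.36 at 6 µM against 0 µM and 0.1, 0.1, 0.1 and 0.15 between the doses, and SPTAN1 -0.32, -0.32, -0.32 and -0.28 between the doses. NCKAP5 was at -0.08 at 6 µM without replicate 1 at 0 µM. The extracellular matrix list turned to lower without replicate 1 at 0 µM, with an adjusted p of 0.05 at 4 µM (0.05 to 0.95 over the libraries left out), and 0.038 and 0.031 at 4 and 6 µM with the consensus exon value, and the cause was not tested.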

Other observations

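In this part the named genes and the test of sterol-sensing genes were chosen only after their values were seen. Beyond the genes named by rule, others passed the test at 6 µM. IGF1 (chromosome 12, 102402360 to 102481831), a growth factor, was listed at 0 in every library at 0 µM and reached 3.27 ± 1.16 FPKM at 4 µM and 3.73 ± 0.16 at 6 µM (limma adjusted p = 0.0476 and 0.0247, SD over n = 3). IL4I1 (chromosome 19, 49889476 to 49897174), an amino acid oxidase of immune cells, rose from 0.247 ± 0.428 to 4.12 ± 1.05 FPKM at 6 µM (log2 difference 2.06 ± 0.33, adjusted p = 0.0497), and RUNX3 (chromosome 1, 24899512 to 24930303), a transcription factor, from 13.1 ± 0.776 to 34.6 ± 8.79 (1.31 ± 0.21, adjusted p = 0.0497). BAMBI (chromosome 10, 28677457 to 28682881), a decoy receptor for TGF-beta family signals, rose from 42.3 ± 3.5 to 82.2 ± 4.68 FPKM (0.94 ± 0.14, adjusted p = 0.0464). With the replicate number as a block the adjusted p at 6 µM was 0.053 for IGF1, 0.081 for IL4I1, 0.059 for RUNX3 and 0.065 for BAMBI.

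ACLY (chromosome 17, 41866916 to 41919054), which makes acetyl-CoA for lipid synthesis, rose from 110 ± 15.6 to 240 ± 26 FPKM at 6 µM (log2 difference 1.12 ± 0.15, limma adjusted p = 0.0412; 0.59 with the consensus exon value, adjusted p = 0.044), and RNF145 (chromosome 5, 159157408 to 159209779), a ubiquitin ligase that acts in sterol regulation, from 35.7 ± 2.2 to 77.2 ± 12.3 (1.08 ± 0.17, adjusted p = 0.0497). Among falling genes FAM83D (chromosome 20, 38926274 to 38953448), a spindle protein, went from 41.5 ± 2.96 to 20.1 ± 3.18 FPKM (-1.02 ± 0.15, adjusted p = 0.0464), and SMC3 (chromosome 10, 110567670 to 110604622), a cohesin subunit, from 38.4 ± 5.91 to 15.9 ± 2.22 (-1.22 ± 0.18, adjusted p = 0.0464), though SMC3 differed by -0.66 with the consensus exon value (adjusted p = 0.067). With the replicate number as a block the adjusted p was 0.065 for ACLY, 0.059 for RNF145 and 0.053 for FAM83D and SMC3. Some genes past the test only with the consensus exon value were MCL1 (chromosome 1, 150574505 to 150579660), an inhibitor of cell death, at 84 ± 2.21 FPKM at 0 µM and 53.7 ± 3.42 at 6 µM (adjusted p = 0.028 with that value), and GDF15 (chromosome 19, 18385752 to 18389176), a stress-induced cytokine, at 25.7 ± 11.2 and 77.3 ± 21.7 FPKM (adjusted p = 0.045).

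Higher cholesterol synthesis genes could come from less sterol at the sterol sensor of the cell, a hypothesis under which targets of LXR, a receptor activated by sterols, would be lower too. Of 8 LXR targets fixed for this test 7 were measured, and 1 of them, APOC1, was known to be high when the test was chosen. Their median log2 difference at 6 µM was 0.34 (SD of members 0.57), and 0.13 with the consensus exon value (SD 0.67). All measured members but ABCA1 were higher with the summed value, and all but ABCA1 and MYLIP with the other. Neither median was negative, where the hypothesis asks for lower targets. The medians lay within the spread of the members, so the hypothesis stays open. ABCA1 was at -0.07, MYLIP at 0.32, LPCAT3 at 0.23, SMPDL3A at 0.34 and NR1H3 at 1.18, and APOE at 1.03 (limma adjusted p = 0.0615). With the consensus exon value MYLIP turned to -0.28. APOC1, at 1.44, was the single member that passed with the summed value, and APOE passed with the other (adjusted p = 0.034). Direct activation of SREBP and a change in sterol transport were not tested.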
